A study of Rattus norvegicus with 12 samples.

How the data were processed

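Expression was measured on Affymetrix Rat Genome 230 2.0 arrays, and the values compared here are the intensity values deposited by the authors. Per the submitters' processing notes, the images were read with GCOS 1.4 and each probe set was summarised by MAS5 to a linear signal, the unit used below. The 2% trimmed mean was 100.03 on every one of the 12 arrays, so the deposited signal had already been scaled array by array. No further normalization was applied. Scanner values per probe and detection calls were not used here. The run records of the arrays were used only to find which arrays had been washed together.

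The table held 31099 probe sets, of which 57 control probe sets were left out. Annotation by Entrez gene ID gave 1 gene symbol to 20832 probe sets (14218 genes) and several symbols to 436, and 9831 stayed unnamed. The gene ID of 20764 probe sets was found in the RefSeq gene table of the rat, and 0 symbols had to be updated. Probe sets among the lowest 40% by mean signal over all 12 arrays (a mean under 17.4) were left out, which kept 18625. Values were analysed as log2(signal + 16). The added constant damps the noise of dim probe sets and understates their fold changes, so a fold given below for a dim gene is smaller than the ratio of its mean signals.

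One limma model with a mean for each of the 4 groups was fitted to all 12 arrays (lmFit, contrasts.fit and eBayes with a mean-variance trend), leaving 8 residual degrees of freedom. The comparisons drawn from it were TsA minus vehicle in each structure, the average of both effects, the difference between them, and nucleus accumbens minus anterior cingulate cortex averaged over treatments. Tests were two-sided, with Benjamini-Hochberg adjustment over the 18625 probe sets and a threshold of 0.05 on the adjusted p. Standard errors (SE) are those of the moderated fit, and SD is that of the signal between arrays.

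The 36 gene lists cover pathways tied to cocaine, to synapses and to histone acetylation and DNA methylation, basic cell functions, and markers of cell types and of neighbouring regions. The 35 lists with at least 5 measured genes were tested with limma's camera, with 1 probe set per gene (the brightest), 10382 genes in all, and an adjustment over the lists of a comparison. The list of blood markers had 3 measured genes and was not tested. The list named GABA receptors also holds genes that encode no receptor, among them Gad1 and Slc12a2. Of the listed symbols, 33 were matched through a synonym. Camera was run with its preset correlation between genes, 0.01, and again with the correlation estimated for each list. Fry was run beside it: it tests whether the genes of a list move on balance one way, and does not compare them with other genes. Members that passed are counted with adjustment over all probe sets and with p adjusted over the list alone.

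The model, filter, lists, alternatives and the rule for naming genes were fixed before the data were examined. For each comparison the rule names, with 1 probe set per gene, the 12 highest and 12 lowest log2 fold changes among probe sets that passed. Where fewer than 10 passed, it names the 8 higher and 8 lower with the smallest p among those whose groups of arrays did not overlap and whose log2 change was at least 0.4 in size, as values only. For a list past the threshold it names the 4 members with the smallest p in the list's direction. Members of the lists of immediate-early genes, histone deacetylases and acetyltransferases, DNA methylation, genes that respond to deacetylase inhibitors, dopamine signalling and neurotrophins may be named in the treatment comparisons, and marker genes in the comparison of structures. Where another probe set of a named gene gave a value of the other sign, or of a size under 0.5 times or over 2 times, bounds set after the data were seen, that value is given too.

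The model was tested by adding known changes to probe sets drawn at random on the real arrays, 67 for each size given here. With a change of 1 on the log2 scale, 95.5% of the changed probe sets were found for TsA in the cingulate cortex, 91.0% in the accumbens, 97.0% for the average and 67.2% for the difference. With a change of 0.5 these shares were 29.9%, 35.8%, 67.2% and 0%. For the comparison of structures, tested on simulated arrays, the shares were 100% and 68.7%. On simulated arrays a list of 20 genes each shifted by 0.3 was called in every comparison, with 0 of the 35 other lists called. The simulated noise was independent between genes. Genes move together on the real arrays, so this does not test how often camera calls a list falsely there. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.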

Results

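Gene expression was measured in 2 brain structures, the anterior cingulate cortex and nucleus accumbens, of male Wistar rats that had self-administered cocaine (0.3 mg/kg per injection, in 40 µl) during 4 daily 2 h sessions, with death 2 h after the last. The rats received either vehicle or a treatment given in the labels only as TsA. TsA is a usual abbreviation of trichostatin A, an inhibitor of histone deacetylases, and lists of genes of histone acetylation were included for that reason, although the labels do not spell the name out. Each of the 12 arrays carried biotin-labelled cRNA made from 6 µg of total RNA of a pool of 2 rats. There were 3 arrays per structure and treatment, so 3 separate pools per group. The number of arrays limits the precision of every value below. Whether the cortex and accumbens pools came from the same rats is not stated.

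The median signal of an array lay between 26.8 and 33.1. Arrays of 1 group correlated with each other at 0.948 to 0.993 across probe sets, and arrays of different structures at 0.865 to 0.938. The first principal component held 67.4% of the variance and parted the structures, and the second held 15.8%. Within the groups, 50.3% of the remaining variance lay along 1 axis, found separately in the cortex arrays and in the accumbens arrays with loadings that correlated at 0.711 across probe sets (genes are not independent replicates). If pools of both structures came from the same rats, the 2 sets of arrays are not independent either. Vehicle arrays were spread along the axis more widely than TsA arrays. Scores of the vehicle arrays were 10.8, -25.9 and -9.30 in the cortex and 25.4, 1.83 and -19.4 in the accumbens. Those of the TsA arrays were 13.3, -2.41 and 13.5 in the cortex and -3.26, -1.28 and -3.31 in the accumbens. The median SD of log2 signal between the arrays of a group was 0.147 for cortex vehicle, 0.111 for cortex TsA, 0.180 for accumbens vehicle and 0.114 for accumbens TsA. The arrays had been washed in 3 batches of 4. Batch 1 held the 3 cortex vehicle arrays and cortex TsA array 1. Batch 2 held cortex TsA arrays 2 and 3 with accumbens vehicle arrays 1 and 2, and batch 3 held accumbens vehicle array 3 with the 3 accumbens TsA arrays. Treatment was thus largely confounded with wash batch in both structures.

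**Figure D1:**
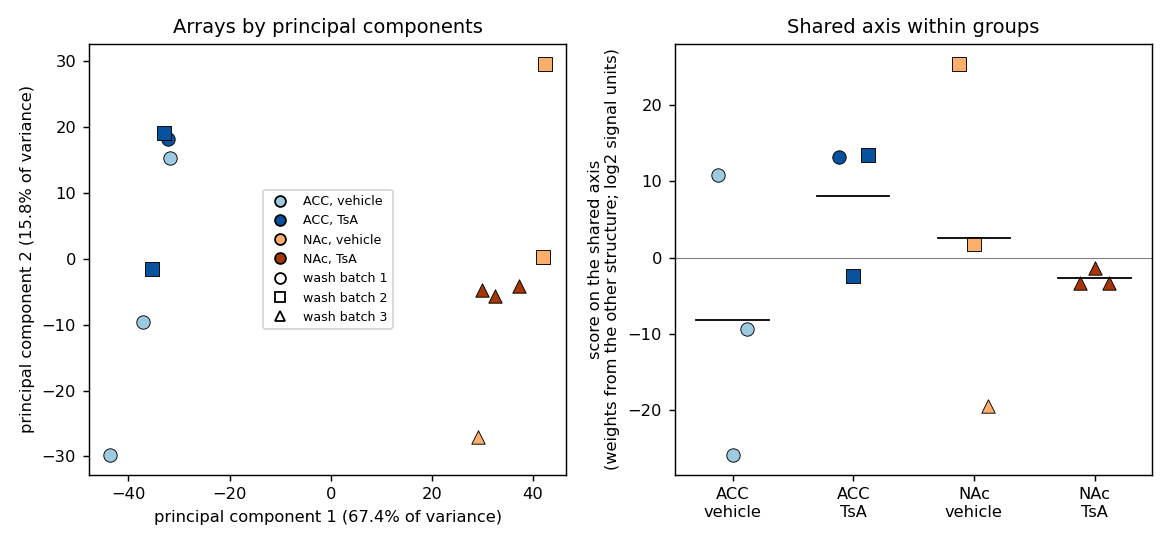
Left, each array on the first (67.4% of variance) and second (15.8%) principal components of log2 signal. Right, the score of each array on the axis of variation within groups, taken from the arrays of the other structure (line, group mean; symbol, wash batch): scores of vehicle arrays run from -25.9 to 25.4 and those of TsA arrays from -3.31 to 13.5.

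The comparison of the structures asks which genes mark the accumbens and the cingulate cortex of these rats, averaged over treatments. The accumbens was marked by genes of the medium spiny neurons, the projection neurons of the striatum. The largest difference on the log2(signal + 16) scale was in Cartpt, which encodes the peptide precursor CART: its signal was 29.3 ± 5.87 (SD, n = 6) in the cortex and 1084 ± 155 in the accumbens, a log2 difference of 4.60 ± 0.11 (SE). Adora2a, an adenosine receptor gene, was higher by 4.38 ± 0.10 (19.9 ± 4.01 against 729 ± 86.6), and the dopamine receptor genes Drd2 and Drd1 by 3.94 ± 0.09 and 3.31 ± 0.09. The cortex was marked by Cyp26b1, which encodes an enzyme that clears retinoic acid, at -3.63 ± 0.10 (420 ± 29.6 in the cortex, 19.6 ± 5.001 in the accumbens; -1.56 at another probe set). Other genes far higher in the cortex were Slc30a3, the zinc transporter of glutamatergic vesicles (-3.37), the peptide genes Grp (-3.34) and Vip (-3.03), and Nrn1, an activity-regulated neuritin (-2.99 ± 0.15, from 1088 ± 69.4 in the cortex to 127 ± 35.2).

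Among the 18625 probe sets tested, 8349 (4952 genes) passed the threshold, 4551 higher and 3798 lower in the accumbens, all with 6 arrays per structure. A difference of at least 2-fold was found for 632 higher and 517 lower probe sets, and one of at least 4-fold for 100 and 69. Also among the highest in the accumbens were Gpr6 (3.90), Nts (neurotensin, 3.83), Syndig1l (3.56), Strip2 (3.53), Rarb (a retinoic acid receptor, 3.51), Pcp4l1 (3.47), Rgs9 (3.38) and Tac1 (the substance P precursor, 3.28). The cortex was also higher in Adra1d (-3.29), Rprm (-3.17), Car10 (-2.94), Dkk3 (-2.85, but -1.52 and -1.68 at other probe sets), C1ql3 (-2.75), Nptxr (-2.74) and the transcription factor gene Neurod1 (-2.74). Mean signals under 17.4, the limit of the filter, were those of Gpr6 (2.02) and Nts (3.32) in the cortex and of Grp (5.69), Adra1d (7.07) and Neurod1 (14.4) in the accumbens, so their values depend on the added constant and understate the difference. The adjusted p of these named genes ranged from 4.07e-12 (Adora2a) to 2.67e-06 (C1ql3). The split between the directions depended on scaling: 54.5% of the changed probe sets were higher in the accumbens as deposited, 47.6% after quantile normalization (3886 higher, 4284 lower) and 37.5% with arrays centred on their medians (3156 higher, 5266 lower). A fixed block for wash batch left 4199 probe sets past the threshold, of which 3696 were among the 8349 and all 3696 kept their direction. Within batch 2 alone, which sets accumbens vehicle against cortex TsA, 4231 passed. In these fits Cartpt stood at 4.58 and 4.51, and Cyp26b1 at -3.96 and -3.84. With array weights 11536 passed.

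**Figure D2:**
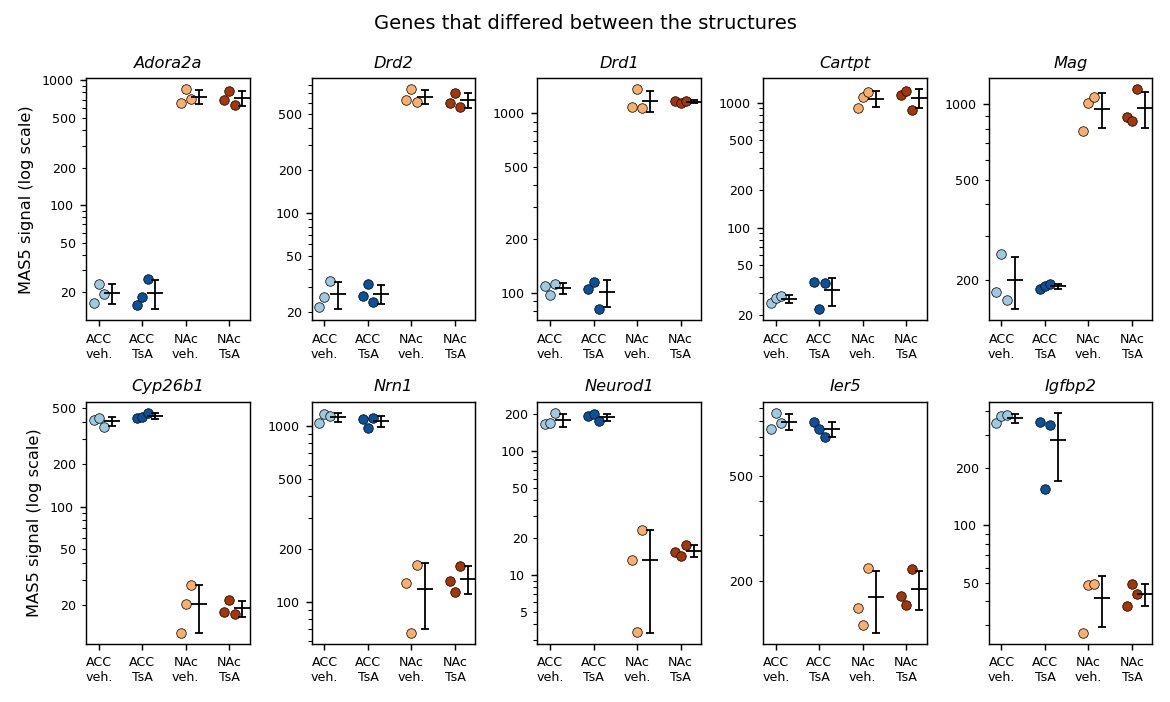
MAS5 signal (log axis) of 10 genes on each of the 12 arrays, by structure and treatment, with the mean and SD of the 3 arrays of each group. Adora2a, Drd2, Drd1, Cartpt and Mag are higher in the accumbens, and Cyp26b1, Nrn1, Neurod1, Ier5 and Igfbp2 in the cortex.

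By lists, camera with its preset correlation called 14 of the 35, 6 higher and 8 lower in the accumbens. With estimated correlations 0 were called, and fry called 24 (12 in each direction). All 27 striatal projection neuron markers were higher, with a median of 2.31 (adjusted p = 5.49e-28, and adjusted p = 0.0537 with an estimated correlation); 20 of them are also in another list. Of 23 genes of dopamine signalling 19 were higher and 3 lower (4 adjusted over the list alone), with a median of 2.56 (adjusted p = 9.63e-14, and adjusted p = 0.133 with an estimated correlation). Of these 23 genes 16 are also in another list, so this call and that of the striatal markers may rest partly on the same genes. Not all dopamine genes were higher. Those higher included Ppp1r1b (DARPP-32, the main phosphatase regulator downstream of dopamine receptors, 3.06), Penk (3.03) and Pdyn (3.50), while Rgs4 (-1.55), Prkar1b (-0.66) and Maob (-0.27) were lower. All 25 oligodendrocyte markers were higher, with a median of 1.67 (adjusted p = 1.28e-18, and adjusted p = 0.113 with an estimated correlation), among them the myelin genes Mag (2.21 ± 0.11, from 195 ± 30.3 to 959 ± 139), Mobp (1.68), Bcas1 (1.98) and Hapln2 (1.89), with a smaller change in Mbp (0.40, but -0.13 and 1.33 at other probe sets). Of 40 genes of the cytosolic ribosome 32 were higher and 0 lower (34 adjusted over the list alone), with a median of 0.27 (adjusted p = 4.60e-08, and adjusted p = 0.436 with an estimated correlation), for example Rps3a (0.57) and Rps28 (0.53). Of 10 markers of septum, pallidum and diencephalon 6 were higher, led by Nts, Calcr (2.25) and Ecel1 (1.75), whose cortex signals were also under 17.4 (2.80 and 10.2), and 2 lower, Slc17a6 (-0.80) and Trpc4 (-0.68), with a median of 0.77 (adjusted p = 0.0275, and adjusted p = 0.218 with an estimated correlation). This call ended with array weights (adjusted p = 0.0646), and the median was 0.158 with dim genes kept.

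Markers of oligodendrocyte precursors were higher for 8 of 12 genes, such as Sox10 (1.53) and Olig1 (1.23), and lower for Cspg5 (-0.41), with a median of 0.35 (adjusted p = 0.0394, and adjusted p = 0.396 with an estimated correlation). This call did not hold with wash batch as a block (median 0.0875, adjusted p = 0.0966) or in batch 2 alone (0.226, adjusted p = 0.121). It also ended without cortex vehicle array 1 (median 0.311, adjusted p = 0.0541), cortex TsA array 2 (0.369, 0.0538) or accumbens TsA array 3 (0.333, 0.0502).

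Higher in the cortex were 19 of 30 markers of cortical glutamatergic neurons (median -1.26, adjusted p = 9.90e-07, and adjusted p = 0.218 with an estimated correlation), among them Slc17a7 (the vesicular glutamate transporter VGLUT1, -2.44), Fezf2 (-2.11) and Cux2 (-1.94). Of this list 6 genes were higher in the accumbens, led by Foxp2 (2.18) and Bcl11b (1.54), which medium spiny neurons also express. Genes of the presynaptic vesicle were lower in the accumbens for 24 of 31 and higher for 2 (median -0.46, adjusted p = 7.25e-07, and adjusted p = 0.218 with an estimated correlation), for example Stx1a (-2.67) and Syn1 (-1.11), and the median was -0.70 with wash batch as a block. Of 17 markers of the meninges and fibroblasts 16 were lower (median -0.87, adjusted p = 1.42e-06, and adjusted p = 0.436 with an estimated correlation), led by Igfbp2 (-2.49 ± 0.17) and Slc13a4 (-1.25), and Bgn was higher (0.19). Immediate-early genes, which neurons switch on within minutes to hours of firing, were lower in the accumbens for 18 of 27 and higher for Rgs2 (0.64), with a median of -0.39 (adjusted p = 3.43e-06, and adjusted p = 0.221 with an estimated correlation). Signal fell from 773 ± 55.5 in the cortex to 181 ± 35.8 in the accumbens for Ier5, from 719 ± 122 to 312 ± 74.7 for Arc, and from 446 ± 76.7 to 257 ± 45.9 for Fos (n = 6 arrays each). The median of the list was -0.64 with wash batch as a block. Lower in the accumbens were further 14 of 22 genes of hypoxia and glycolysis with 2 higher (median -0.29, adjusted p = 0.000346, and adjusted p = 0.455 with an estimated correlation; Egln3 -1.08, Ldha -0.56), and 12 of 19 genes of cholesterol synthesis with 0 higher (-0.31, adjusted p = 0.00077, and adjusted p = 0.455 with an estimated correlation; Acat2 -0.68). The cholesterol median was -0.52 with wash batch as a block. Of 34 genes of the cytoskeleton and axon 18 were lower and 4 higher (19 and 6 adjusted over the list alone), with a median of -0.18 (adjusted p = 0.00287, and adjusted p = 0.436 with an estimated correlation), for example Basp1 (-1.47) and Stmn2 (-0.82), and the median was -0.31 with wash batch as a block. Feedback genes of the MAPK pathway were lower for 10 of 15 and higher for 3 (median -0.38, adjusted p = 0.0197, and adjusted p = 0.436 with an estimated correlation; Dusp6 -0.95). That call ended with wash batch as a block (adjusted p = 0.0873). Except where a count is given, adjusting over the list alone gave the same counts for these 14 lists.

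The other 21 lists were not called by camera, and fry called 10 of them. The counts below are to be read against the 44.8% of all probe sets that passed. Ion channels had 17 members higher and 20 lower (21 adjusted over the list alone) of 52, glutamate receptors and postsynaptic density genes 13 and 8 of 44, neuropeptides 10 and 8 of 22, and GABA receptors 7 and 4 of 17. Genes of oxidative phosphorylation had 4 higher and 7 lower of 53 (4 and 6 adjusted over the list alone), those of proteasome and ubiquitin 2 and 9 of 32, and endothelial markers 1 and 0 of 25. Counts were 7 and 3 of 24 for glucocorticoid response, 6 and 2 of 23 for heat shock, 0 and 7 of 20 for endoplasmic reticulum stress (6 adjusted over the list alone), 5 and 5 of 20 for the circadian clock, 3 and 0 of 8 for histone genes, 0 and 4 of 13 for interferon and antigen presentation (2 adjusted over the list alone), 3 and 1 of 5 for choroid plexus and ependyma, and 3 and 3 of 15 for neurotrophins. Median and mean differed in sign for the microglia list (0.0865 and -0.00303) and the circadian list (-0.029 and 0.0499).

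**Figure D3:**
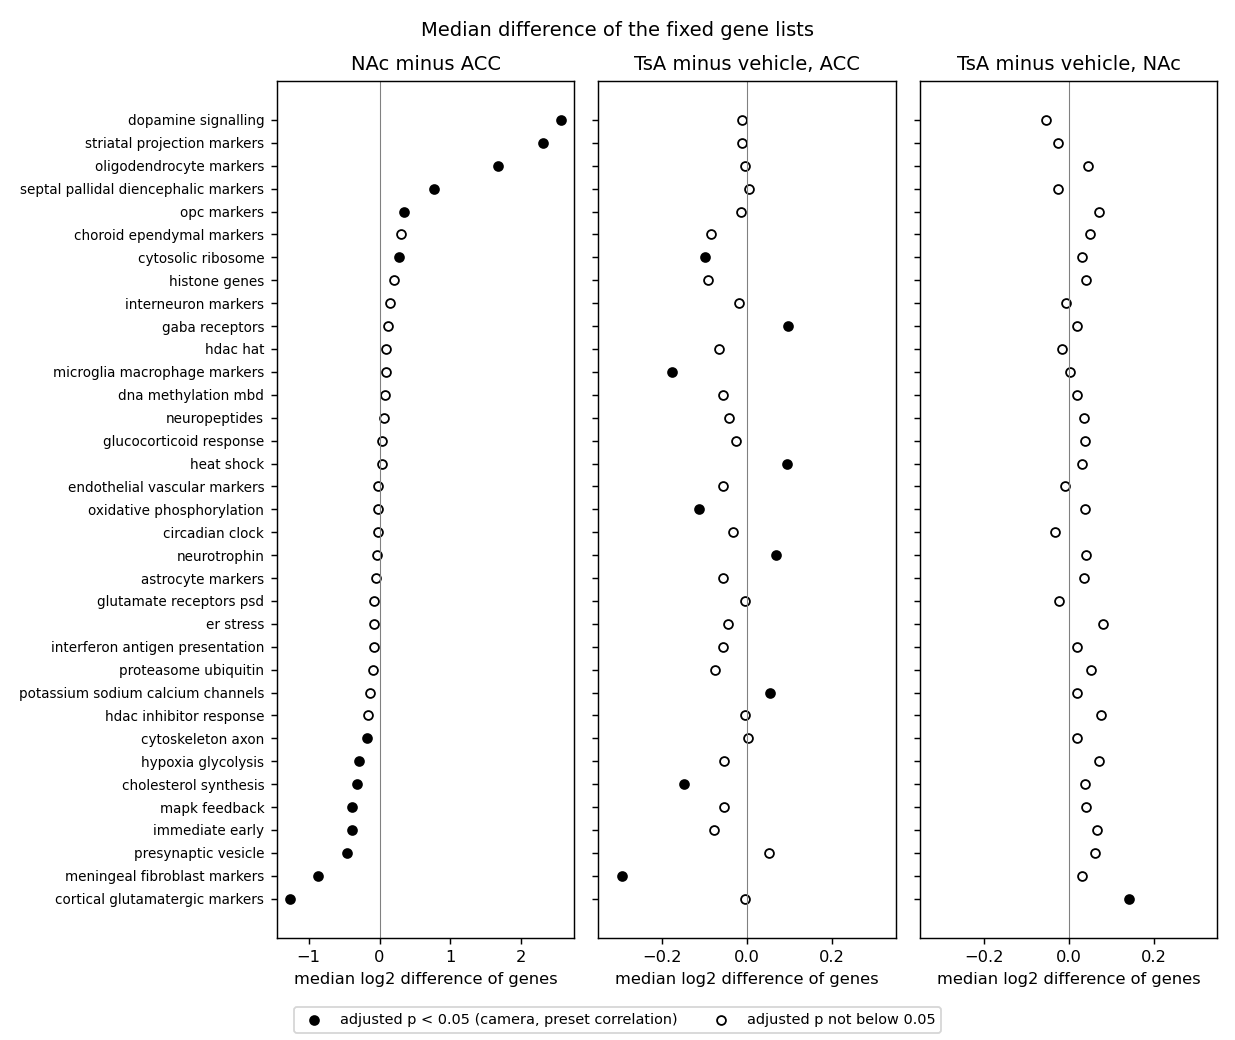
Median log2 difference of the genes of each of the 35 lists, for accumbens minus cortex and for TsA minus vehicle in each structure (filled, camera adjusted p under 0.05 with the preset correlation). Medians run from -1.26 to 2.56 between the structures and from -0.29 to 0.14 for TsA.

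The comparison of TsA with vehicle in the anterior cingulate cortex asks whether the treatment changed expression in the cortex of cocaine-taking rats. No single gene passed the threshold. Among the genes with the smallest p and no overlap between the groups, Dkc1, which encodes a pseudouridine synthase of the telomerase and nucleolar complexes, had a signal of 119 ± 20.02 with vehicle and 62.4 ± 1.80 with TsA (SD, n = 3), a log2 value of -0.78 ± 0.16 (SE). Tnr, which encodes the perineuronal matrix protein tenascin-R, had 38.7 ± 4.54 and 64.5 ± 9.76 (0.55 ± 0.11), and Sacm1l, a phosphoinositide phosphatase gene, 162 ± 59.2 and 266 ± 26.9 (0.71 ± 0.21). Igfbp6, a binding protein of insulin-like growth factors, had 73.7 ± 7.39 and 46.9 ± 1.49 (-0.51 ± 0.10). By gene groups, cholesterol synthesis, ribosome, respiratory chain, microglia and meningeal genes leaned lower with TsA, and genes of GABA receptors, heat shock, ion channels and neurotrophins leaned higher by camera with its preset correlation. With an estimated correlation all 9 of these calls were lost (adjusted p = 0.676 to 0.984), which leaves the medians as they are. With wash batch as a block, which sets 1 TsA array against 3 vehicle arrays, 8 were lost. Medians stayed of similar size for cholesterol synthesis (-0.14 against -0.15), microglia (-0.162 against -0.18) and GABA receptors (0.106 against 0.097). So did those of oxidative phosphorylation (-0.109 against -0.11) and the ribosome (-0.0869 against -0.099). The medians of meningeal markers and neurotrophins shrank, and that of ion channels turned its sign.

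With limma 0 of the 18625 probe sets passed (smallest adjusted p 0.751), 851 had an unadjusted p under 0.05 where chance gives 931.25, and all other settings gave 0 as well except array weights. The groups did not overlap for 2302 probe sets (12.4%), where chance gives 10% for 3 arrays against 3. The median size of change was 0.111 and the largest 2.05. The other higher genes with the smallest p and no overlap were Tafa2 (0.58, but 0.18 and 0.32 at other probe sets), Abca1 (0.45, but 0.063 at another probe set), Chmp2b (0.42), Bbx (0.52), Mdm4 (0.46, but 0.20) and Slc4a4 (0.47, but 0.23). The lower were Tpst1 (-0.56), Pdss2 (-0.43), Mrps9 (-0.56, but 0.16 at another probe set), Fhl2 (-0.42), LOC102554253 (-0.47) and Ddx31 (-0.40). A block for wash batch, which sets cortex TsA array 1 against the 3 vehicle arrays, put Dkc1 at -0.81, Tnr at 0.65, Sacm1l at 0.73 and Igfbp6 at -0.53, with 0 probe sets past the threshold. With array weights, 4519 probe sets passed (2436 higher, 2083 lower), Dkc1 and Tnr among them. That estimation did not converge and gave cortex vehicle array 3 a weight of 7.995.

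**Figure D4:**
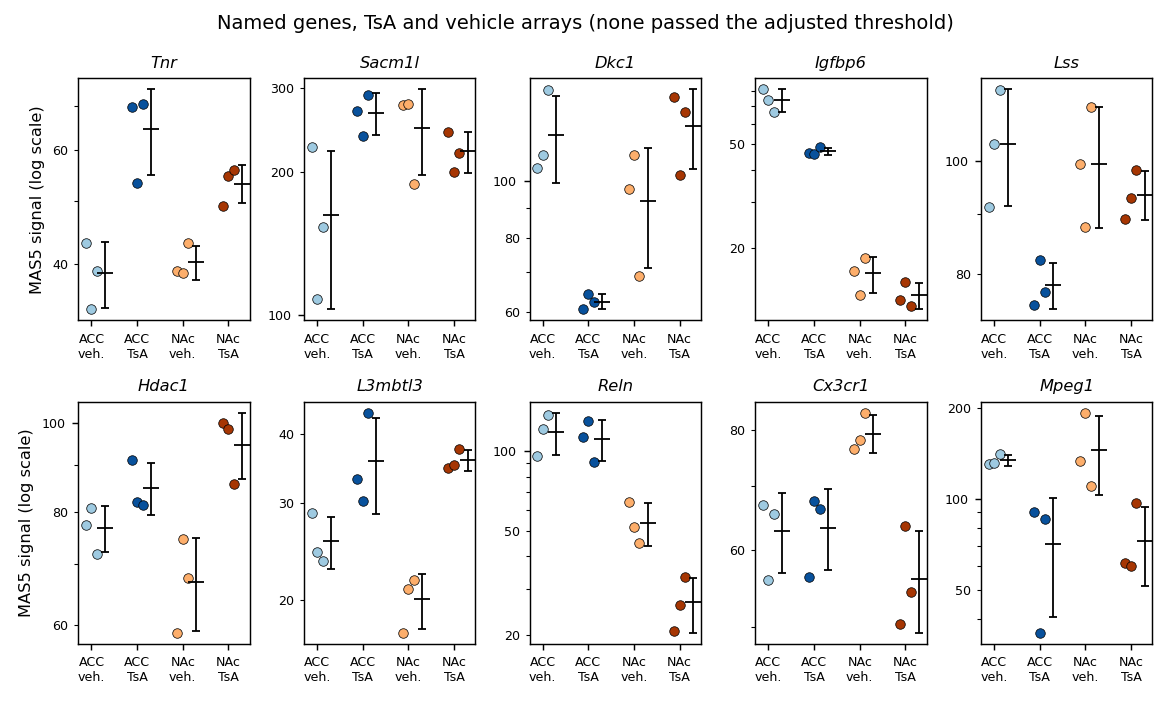
MAS5 signal (log axis) of 10 genes named in the comparisons of TsA with vehicle, on each of the 12 arrays, with the mean and SD of the 3 arrays of each group. None passed the adjusted threshold; Dkc1 has a mean of 119 with vehicle and 62.4 with TsA in the cortex, and Hdac1 of 67.0 and 94.8 in the accumbens.

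Camera with its preset correlation called 9 lists in the cortex, 5 lower and 4 higher with TsA, with 0 members past the threshold over all probe sets. Adjusted over the list alone 0 members of these 9 lists passed, and in the other lists 1 histone gene was lower and 1 precursor marker (Tnr) higher. Genes of cholesterol synthesis were below 0 for 18 of 19, with a median of -0.15 (adjusted p = 0.00948, and adjusted p = 0.984 with an estimated correlation); Lss, the lanosterol synthase gene, stood at -0.34 ± 0.11 and Mvk at -0.32. Ribosomal genes were below 0 for 34 of 40 (median -0.099; Rpl14 -0.21) and those of oxidative phosphorylation for 44 of 53 (-0.11; Ndufb8 -0.27, Cox5b -0.26), each with adjusted p = 0.00948, and adjusted p = 0.984 with an estimated correlation. Of the microglia and macrophage markers 18 of 22 were below 0 (median -0.18, adjusted p = 0.00948, and adjusted p = 0.745 with an estimated correlation; Cd74 -0.47, C1qb -0.35). For meningeal and fibroblast markers it was 14 of 17 (-0.29, adjusted p = 0.00948, and adjusted p = 0.984 with an estimated correlation). Among them Col1a2 stood at -0.46 (but -0.21 at another probe set) and Slc13a4 at -0.43. Col1a2 signals on TsA arrays 1, 2 and 3 were 109, 53.5 and 128 (vehicle 123 to 141). Slc13a4 had 72.4, 38.7 and 86.2 (vehicle 78.7 to 110), and Cd74 64.9, 31.9 and 57.3 (vehicle 69.7 to 79.9). Each was lowest on cortex TsA array 2, and without that array the meningeal and microglia calls were lost. On the list of GABA receptors 12 of 17 genes were above 0 (0.097, adjusted p = 0.00948, and adjusted p = 0.676 with an estimated correlation). Among them were Gabrb2 (0.90 ± 0.50) and Slc12a2 (0.51), which encodes no receptor. Heat shock genes were above 0 for 16 of 23 (0.094, adjusted p = 0.00948, and adjusted p = 0.951 with an estimated correlation; Hspa4l 0.60, Hsp90b1 0.55). Ion channels stood above 0 for 35 of 52 (0.054, adjusted p = 0.0285, and adjusted p = 0.676 with an estimated correlation; Cacnb4 0.63) and neurotrophin genes for 12 of 15 (0.067, adjusted p = 0.0366, and adjusted p = 0.676 with an estimated correlation; Cntf 0.37; Bdnf 0.13, but 0.68 at another probe set). Fry gave an adjusted p of 0.648 for all 9.

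Across probe sets the TsA effect in the cortex correlated at 0.643 with the axis found in the accumbens arrays alone, and the effect in the accumbens at -0.290 with the axis found in the cortex arrays. With the score on the axis as a covariate 4 lists were called: cholesterol synthesis (median -0.069), microglia (-0.097), meningeal markers (-0.247) and presynaptic genes, which are not among the 9. The medians of the 6 calls lost were 0.069 for GABA receptors (adjusted p = 0.319), 0.037 for heat shock (0.462), 0.030 for ion channels (0.156), 0.067 for neurotrophins (0.0926), -0.024 for the ribosome (0.265) and -0.023 for oxidative phosphorylation (0.156). Gabrb2 was the gene with the largest change across the axis (2.30). Blocking on wash batch left 1 list, heat shock (median 0.249); adjusted p was 0.0727 for cholesterol synthesis and microglia, 0.0798 for GABA receptors, 0.286 for oxidative phosphorylation and 0.294 for the ribosome. The medians of the other 3 were 0.0131 for neurotrophins (0.286), -0.0826 for meningeal markers (0.931) and -0.0159, a turned sign, for ion channels (0.519). Batch 1 alone gave the same medians. Array weights left 1 list. Without cortex vehicle array 1 there were 4 lists and without cortex TsA array 2 there were 5, with 8 to 10 without any other array. Calls lost without cortex vehicle array 1 were cholesterol synthesis (adjusted p = 0.178), microglia (0.0909), meningeal markers (0.178), neurotrophins (0.262) and ion channels (0.185). Those lost without cortex TsA array 2 were the ribosome (0.0941), microglia (0.219), meningeal markers (median -0.0885, 0.742) and ion channels (0.169). Oxidative phosphorylation was lost without cortex vehicle array 2 (median -0.0415, 0.125) and heat shock without cortex TsA array 1 (0.0304, 0.230). Ion channels were also lost without cortex vehicle array 2 (0.0629) or cortex TsA array 3 (0.106), and neurotrophins without cortex TsA array 3 (0.118) or accumbens vehicle array 1 (0.056). Among calls that held, leaving out 1 array moved the median to -0.057 for the ribosome (cortex vehicle array 2), -0.117 for microglia and 0.0949 for ion channels (cortex vehicle array 3), 0.120 for ion channels (cortex TsA array 1), and 0.173 for heat shock and 0.0428 for neurotrophins (cortex TsA array 2).

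The lists tied to histone acetylation, to DNA methylation and to cocaine were not called in the cortex. Histone deacetylases and acetyltransferases were below 0 for 23 of 34 genes (median -0.066; Hdac1 0.12, Hdac2 0.065, Ep300 -0.25), and genes known to respond to deacetylase inhibitors had a median of -0.0046. Immediate-early genes were below 0 for 17 of 27 (-0.079; Fos -0.19 ± 0.17, Arc 0.19), genes of dopamine signalling had a median of -0.011 and those of DNA methylation -0.058. For 12 of the lists not called the direction given by camera was up although the median was below 0, immediate-early genes and responders to deacetylase inhibitors among them.

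In the nucleus accumbens the same comparison asks whether TsA changed expression in a main target of the dopamine neurons that cocaine acts on. Again no gene passed the threshold. The histone deacetylase gene Hdac1 had a signal of 67.0 ± 7.85 with vehicle and 94.8 ± 7.85 with TsA (SD, n = 3), a log2 value of 0.42 ± 0.10 (0.36 at another probe set). L3mbtl3, which encodes a reader of methylated histones, had 20.1 ± 2.30 and 35.9 ± 1.57 (0.53 ± 0.11). The microglial gene Cx3cr1, which encodes the fractalkine receptor, had 79.2 ± 3.51 and 56.1 ± 6.76 (-0.41 ± 0.11) and the macrophage gene Mpeg1 145 ± 42.2 and 72.7 ± 21.1 (-0.85 ± 0.26), while the median of all microglia markers was 0.0029. One probe set of Reln, which encodes the matrix protein reelin, had 53.5 ± 9.96 and 26.7 ± 6.23 (-0.71 ± 0.16, and -0.41 at the other).

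With limma 0 probe sets passed (smallest adjusted p 1.00), 408 had an unadjusted p under 0.05 where chance gives 931.25, and all other settings gave 0 except wash batch 3 alone. The groups did not overlap for 1020 probe sets (5.48%, where chance gives 10%). The median size of change was 0.0761 and the largest 0.988. Further genes with small p and no overlap were Tsc22d4 (0.97, but -0.038 at another probe set), Palmd (0.67, but 0.073 and 0.16), Nts (0.49), Pcdh10 (0.44), Rell2 (0.42) and Nop56 (0.42, but -0.063 at another probe set) on the higher side. The lower were Tead2 (-0.57), Ubp1 (-0.53, but -0.10 and -0.073), C2h1orf52 (-0.49), Atosa (-0.46) and Lrrc23 (-0.41, but -0.15 at another probe set). In batch 3 alone, where 3 TsA arrays face 1 vehicle array, 6 probe sets passed, all higher. Blocking on wash batch put Hdac1 at 0.40, L3mbtl3 at 0.46, Cx3cr1 at -0.46, Mpeg1 at -0.53 and Reln at -0.52.

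In the accumbens 1 list was called, markers of cortical glutamatergic neurons, above 0 for 28 of 30 genes with a median of 0.14 (adjusted p = 0.0109, and adjusted p = 0.837 with an estimated correlation; fry 0.813). Over all probe sets 0 members passed, and 0 adjusted over the list alone. Neurod2 stood at 0.40 ± 0.26, Tbr1 at 0.32 ± 0.20 and Rasgrf2 at 0.23 ± 0.13. With wash batch as a block, and in batch 3 alone, the median was -0.046. The call ended without accumbens vehicle array 2 (median 0.0219, adjusted p = 0.736), accumbens TsA array 1 (0.115, 0.0952) or accumbens TsA array 3 (0.0918, 0.279), and without accumbens vehicle array 3 the median was 0.219. The number of lists called was 0 without accumbens TsA array 1, 7 without accumbens TsA array 2, 4 without accumbens TsA array 3, 3 without accumbens vehicle array 1, 3 without accumbens vehicle array 2 and 2 without accumbens vehicle array 3.

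Of the lists not called in the accumbens, immediate-early genes were above 0 for 20 of 27 (median 0.067; Fos 0.26 ± 0.17, Dusp1 0.44 ± 0.28, but 0.19 at another probe set) and responders to deacetylase inhibitors for 19 of 27 (0.077; Hspa1a 0.53). Histone deacetylases and acetyltransferases were below 0 for 20 of 34 (-0.015; Hdac10 -0.30, Crebbp -0.22, but -0.087 at another probe set), and genes of dopamine signalling for 16 of 23 (-0.052; Drd1 -0.0060, Drd2 -0.085). The value of Hspa1a rests largely on TsA array 1, with signals of 174, 75.7 and 57.0 with TsA and 92.7, 42.0 and 50.6 with vehicle. Medians were 0.041 for neurotrophins (Bdnf 0.20) and 0.019 for DNA methylation. Camera's direction was down with a median above 0 for DNA methylation, histone genes, meningeal markers and microglia, and up with a median below 0 for markers of septum, pallidum and diencephalon.

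Averaging the TsA effect over both structures gives its mean, which a change in 1 structure alone can move. The naming rule gave 4 genes: Tnr (0.43 ± 0.08) and L3mbtl3 (0.42 ± 0.08) were higher, and Mpeg1 (-0.86 ± 0.18) and Pop5 (-0.63 ± 0.16, but -0.053 at another probe set) lower. None passed (adjusted p = 0.556 for the first pair). The smallest adjusted p of any probe set was 0.219, at one without a gene symbol. With limma 0 probe sets passed, 515 had an unadjusted p under 0.05 where chance gives 931.25, array weights gave 103 and all other settings 0. Across probe sets the effects in cortex and accumbens correlated at -0.170.

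Camera called 9 lists for the average, with 0 members past the threshold over all probe sets or adjusted over the list alone, and fry gave an adjusted p of 0.804 for each of the 9. Lower were microglia (18 of 22 below 0, median -0.10, adjusted p = 0.00573, and adjusted p = 0.625 with an estimated correlation; Cx3cr1 -0.20), meningeal markers (14 of 17, -0.13, adjusted p = 0.0188, and adjusted p = 0.716 with an estimated correlation) and cholesterol synthesis (15 of 19, -0.056, adjusted p = 0.0421, and adjusted p = 0.716 with an estimated correlation). Heat shock genes were higher (18 of 23 above 0, median 0.081, adjusted p = 0.00573, and adjusted p = 0.663 with an estimated correlation; Hspa1a 0.44, Hspa2 0.25, but 0.085 at another probe set). So were genes of the presynaptic vesicle (27 of 31, 0.044, adjusted p = 0.0122, and adjusted p = 0.716 with an estimated correlation; Napb 0.15) and GABA receptors (15 of 17, 0.073, adjusted p = 0.0192, and adjusted p = 0.625 with an estimated correlation). Neurotrophins stood above 0 for 11 of 15 (0.054, adjusted p = 0.0202, and adjusted p = 0.496 with an estimated correlation) and cortical glutamatergic markers for 22 of 30 (0.075, adjusted p = 0.0230, and adjusted p = 0.716 with an estimated correlation). Ion channels stood above 0 for 34 of 52 (0.034, adjusted p = 0.0421, and adjusted p = 0.625 with an estimated correlation). The value of Hspa1a rests largely on TsA array 1 of each structure. Its signals with TsA were 113, 68.1 and 52.1 in the cortex and 174, 75.7 and 57.0 in the accumbens. Within the structures, microglia had a median of -0.18 in the cortex and 0.0029 in the accumbens. For meningeal markers these were -0.29 and 0.031, for cholesterol synthesis -0.15 and 0.037, and for cortical markers -0.0042 and 0.14. The other lists called had medians above 0 in both structures. Blocking on wash batch left 4 lists, and the medians of cortical markers (-0.052), presynaptic genes (-0.041) and ion channels (-0.0072) turned. There were 3 lists without cortex vehicle array 1, 4 without cortex TsA array 2, and 6 to 12 without any other array. Heat shock was lost without cortex TsA array 1 (adjusted p = 0.062), accumbens vehicle array 3 (0.159) or accumbens TsA array 1 (0.0905), and microglia without cortex TsA array 2 (0.0689). Cholesterol synthesis was lost without cortex vehicle array 1 (0.190), cortex TsA array 3 (0.150), accumbens vehicle array 1 (0.0755) or 3 (0.432, median 0.00185), or accumbens TsA array 1 (0.0905) or 2 (0.223). The cortical markers were lost without cortex vehicle array 1 (0.106), cortex TsA array 2 (0.0729), accumbens vehicle array 2 (0.633, median -0.0116) or accumbens TsA array 3 (0.314). GABA receptors were lost without cortex vehicle array 2 (0.0532), cortex TsA array 3 (0.0566) or accumbens vehicle array 3 (0.472). For meningeal markers these were cortex vehicle array 1 (0.137), cortex TsA array 2 (0.764), accumbens vehicle arrays 1 (0.0519) and 3 (0.0877) and accumbens TsA array 1 (0.0712). For neurotrophins they were cortex vehicle array 1 (0.137, median -0.000995), cortex TsA array 3 (0.0566), accumbens vehicle array 3 (0.192) and accumbens TsA array 3 (0.126). For presynaptic genes they were cortex vehicle array 1 (0.160), cortex TsA array 2 (0.0689), accumbens vehicle array 1 (0.0519) and accumbens TsA array 3 (0.336). Ion channels were lost without cortex vehicle array 1 (0.159) or 2 (0.105), cortex TsA array 2 (0.111) or 3 (0.123), accumbens vehicle array 2 (0.100) or 3 (0.245) or accumbens TsA array 3 (0.254). Among calls that held, medians moved to -0.031 for cholesterol synthesis and 0.0516 for heat shock (without cortex vehicle array 2), 0.104 for neurotrophins and 0.0525 for ion channels (cortex vehicle array 3), 0.0535 for ion channels (cortex TsA array 1), 0.0289 for neurotrophins (cortex TsA array 2), 0.122 for cortical markers and -0.053 for microglia (accumbens vehicle array 3), and 0.114 for cortical markers and 0.0731 for presynaptic genes (accumbens TsA array 2).

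The difference between the TsA effects, accumbens minus cortex, asks whether the structures responded differently. No gene passed the threshold, in this test or in either structure, and the values below are those the naming rule gave. Tbc1d25 stood at -0.32 in the cortex and 0.27 in the accumbens (difference 0.59 ± 0.15), and Htr1a, the serotonin 1A receptor, at -0.22 and 0.27 (0.49 ± 0.13), the latter from accumbens signals of 6.50 and 11.1, which are under the 17.4 of the filter. Erf, a repressor of the ETS family, differed by 0.66 ± 0.20 and the cytokine gene Tslp by -0.60 ± 0.18. Accumbens signals of Tslp with TsA were 13.4, 14.3 and 15.1, also under 17.4. Further values were 0.54 for Cebpa (but -0.20, 0.074 and -0.0074 at other probe sets), 0.52 for Trpv2, 0.52 for Slc6a20a, 0.48 for Mmp15, 0.44 for Eri3, -0.43 for Ncapd3 and -0.41 for Lrp8. With limma 0 probe sets passed (smallest adjusted p 0.840), 662 had an unadjusted p under 0.05 where chance gives 931.25, array weights gave 969 and all other settings 0. Camera called 3 lists: cholesterol synthesis (17 of 19 above 0, median 0.181, adjusted p = 0.0468), the ribosome (35 of 40, 0.131, adjusted p = 0.0399) and oxidative phosphorylation (43 of 53, 0.161, adjusted p = 0.0399), each with adjusted p = 0.893 with an estimated correlation, and 0 members passed, over all probe sets or adjusted over the list alone. With wash batch as a block none of the 3 was called, and the medians were -0.030, 0.0439 and 0.047. There were 0 lists without cortex vehicle array 1, cortex TsA array 2, accumbens vehicle array 1 or accumbens TsA array 1, 1 without cortex vehicle array 2, 5 without cortex TsA array 1 or accumbens TsA array 2, and 2 to 4 without any other array. Cholesterol synthesis was lost without cortex vehicle array 1 (adjusted p = 0.217), cortex TsA array 2 (0.0836) or 3 (0.102), accumbens vehicle array 1 (0.0996) or 2 (0.320), or accumbens TsA array 1 (0.146) or 3 (0.190), and its median was 0.278 without accumbens vehicle array 3. The ribosome and oxidative phosphorylation were lost without the same 6 arrays, with adjusted p for each list in turn: cortex vehicle array 1 (0.0591 for both), cortex vehicle array 2 (0.0752, 0.110), cortex TsA array 2 (0.118, 0.0856), accumbens vehicle array 1 (0.434, 0.240), accumbens vehicle array 3 (0.0754, 0.0679) and accumbens TsA array 1 (0.381, 0.212).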

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

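The results here come from the planned test of the difference between the structures, and no test of them was chosen after the result was seen. Chosen from that comparison were 3 gene lists whose response to TsA differed between accumbens and cortex by camera with the preset correlation. For cholesterol synthesis the TsA effect in the accumbens minus that in the cortex had a median of 0.181 on the log2 scale (medians of 0.037 in the accumbens and -0.15 in the cortex). Ribosomal genes gave 0.131 (0.031 and -0.099). Oxidative phosphorylation gave 0.161 (0.039 and -0.11). None of these 3 differences stayed past the threshold with an estimated correlation, after quantile normalization, with arrays centred on their medians, or with wash batch or replicate number as a block. An estimated correlation or replicate number as a block leaves these medians as they are, so those calls ended through p and not size. The medians, in the same order, were 0.185, 0.109 and 0.142 after quantile normalization and 0.209, 0.159 and 0.189 with arrays centred on their medians. With wash batch as a block they were -0.030, 0.0439 and 0.047.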

How the results depend on the processing

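Chosen after the data were seen were the score on the shared axis as a covariate, the farthest array of each structure left out, single wash batches, wash batch as a random block, and the check of replicate numbers on the most variable probe sets; all other alternatives were planned. Of the values of named genes and lists under the alternatives, 6488 kept their direction and their side of the threshold, 60 passed it (all with array weights), 228 no longer passed it and 21 turned. Of the 6488, 2802 came from fits without 1 array. No gene named for TsA had passed to begin with (smallest adjusted p of any probe set by limma 0.219), so staying on that side says little. The comparisons within both structures together have no alternative that fits only their own arrays, since these are all 12.

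The count of probe sets changed by TsA was 0 in every comparison under other pseudocounts (1 and 64), filters, scalings and variance trends, and with wash batch, shared animals or replicate number as a block. Array weights gave 4519 in the cortex, 103 for the average and 969 for the difference, and arrays of wash batch 3 alone gave 6 in the accumbens with 1 vehicle array. Between the structures the count of 8349 became 4199 with wash batch as a fixed block and 4231 in batch 2 alone, where fewer arrays or degrees of freedom are left. It was 8029 with wash batch as a random block and 9286 with shared animals as a random block (correlations within blocks of 0.0389 and 0.197). Without any 1 array it ranged from 7509 (accumbens TsA array 2) to 9048 (accumbens vehicle array 3), and the counts for TsA ranged from 0 to 0.

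The numbers of lists called were 9 (cortex), 1 (accumbens), 9 (average), 3 (difference) and 14 (structures). With an estimated correlation all became 0, and fry gave 0 for the first 4 and 24 for the structures. In the cortex they became 1 with array weights, 1 with wash batch as a fixed block, 1 in batch 1 alone and 4 with the axis score as a covariate. In the accumbens they became 4 with array weights, 5 with wash batch as a fixed block, 4 with the farthest array of each structure left out and 2 in batch 3 alone. For the average they became 5 with no filter and 4 with wash batch as a fixed block. For the difference they became 0 with the lowest 60% left out, quantile normalization, median centring, replicate block or wash batch as a fixed block, and 1 with the axis score as a covariate. Leaving out 1 array gave 4 (without cortex vehicle array 1) to 10 lists in the cortex, 0 (accumbens TsA array 1) to 7 (accumbens TsA array 2) in the accumbens, 3 (cortex vehicle array 1) to 12 for the average, 0 (cortex vehicle array 1, cortex TsA array 2, accumbens vehicle array 1 or accumbens TsA array 1) to 5 for the difference, and 13 to 15 between the structures. Apart from the smaller numbers of arrays, the cause was not tested.

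Medians and genes that turned did so as follows. With array weights, ion channels in the cortex went to -0.0266 and Ptk2b for the average to -0.0415. With wash batch as a fixed block, ion channels in the cortex went to -0.0159, and in the accumbens the cortical glutamatergic markers to -0.0457, Tbr1 to -0.0372 and Neurod2 to -0.262; batch 1 alone and batch 3 alone gave these same 4 values. Under that block the average turned for cortical glutamatergic markers (-0.0517), ion channels (-0.00719) and presynaptic genes (-0.0412). The difference turned under it for cholesterol synthesis (-0.0296), Dhcr7 (-0.0724) and Nsdhl (-0.00971). Without the block Nsdhl stood at 0.33 for the difference, but at -0.19 at another probe set. For the average, leaving out 1 array moved neurotrophins from -0.000995 (without cortex vehicle array 1) to 0.104 (cortex vehicle array 3), cortical glutamatergic markers from -0.0116 (accumbens vehicle array 2) to 0.122 (accumbens vehicle array 3), Gad2 from -0.0285 (accumbens vehicle array 3) to 0.317 (accumbens vehicle array 2), and cholesterol synthesis from -0.0882 (accumbens vehicle array 1) to 0.00185 (accumbens vehicle array 3). Gabrg1 in the cortex went to -0.0722 with the axis score as a covariate. The cause was not tested.

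Pairing by replicate number was checked through the correlation of arrays with the same number, after centring on groups. Between vehicle and TsA it was 0.337, 0.482 and -0.114 in the cortex for numbers 1, 2 and 3. In the accumbens it was -0.0748, -0.0626 and 0.0563. Other ways of matching were not counted within a structure, so pairing there is neither shown nor excluded. Between cortex and accumbens the correlation was 0.663, 0.0762 and 0.0875 with vehicle and 0.117, 0.0308 and 0.163 with TsA. All were above 0 but only 3 of 6 over 0.1. Of the 36 ways of matching the numbers within treatments, 4 gave a sum as high. On the 100 probe sets that varied most within the cortex groups it was 0.880, 0.561 and 0.558 with vehicle and 0.624, 0.370 and 0.649 with TsA, each of the 12 arrays correlated best with its own number among the 3 arrays of its treatment in the other structure, and 1 of 36 matchings, the real one, gave a sum as high (share 0.0278). With 50 or 200 probe sets all 12 did so too, and with 500 it was 10. This is a hint from the data, not the design, that pools with the same number and treatment came from the same rats, and shared rats stay open. If they are shared, the average over structures counts the same 3 pools per treatment again; the fit with shared animals as a random block gave it 0 probe sets, and camera takes no random block, so its list calls were not tested that way. With replicate number as a block the counts of probe sets were 0 for each TsA comparison and 8995 between the structures, and 9, 1, 9, 0 and 13 lists were called. Signal over background limits the dim genes: among the 12417 probe sets left out by the filter, 0 were called for TsA and 1352 between the structures when they were tested.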

Other observations

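Tests of the shared axis against RNA quality, wash batch and cell makeup, of the cortical markers within wash batch 3, and of splits without the group means were chosen after the result was seen, and the other tests before.

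Some genes of chromatin differed between the structures, which also differ in cell makeup. All 25 oligodendrocyte markers, for example, were higher in the accumbens (median 1.67). Whether cell makeup gives the values below was not tested. Camera called none of the 3 lists named here, and fry called each (adjusted p = 0.00327 for histone deacetylases and acetyltransferases, 0.00019 for DNA methylation and 0.000599 for genes that respond to deacetylase inhibitors). Over all probe sets tested 44.8% passed, so the counts of the first 2 lists below do not set them apart from other genes. Of 34 histone deacetylases and acetyltransferases, 10 were higher in the accumbens and 4 lower (n = 6 arrays per structure). The acetyltransferase gene Kat2b was higher by 1.01 on the log2 scale (119 ± 14.0 SD in the cortex, 255 ± 30.7 in the accumbens), the deacetylase genes Sirt2 by 0.96 (498 against 983) and Hdac11 by 0.70 (477 against 785), and Hdac1 and Hdac2 by -0.01 (0.02 at another probe set) and 0.07. Of 14 genes of DNA methylation, 4 were higher (Mbd2 0.65, Tet3 0.52, Tet2 0.47, Gadd45a 0.43) and Gadd45b was lower (-0.32). Of 27 genes that respond to deacetylase inhibitors, 5 were higher and 11 lower, and the lowest was Bdnf, the brain-derived neurotrophic factor (125 ± 19.5 in the cortex, 14.8 ± 4.50 in the accumbens, -2.20, but -0.79 at another probe set). Another gene of neurotrophic signalling, the receptor gene Gfra2, stood at -2.02.

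Among 17 interneuron markers 8 were higher in the accumbens and 4 lower, and no test of subtypes was run. Higher were the GABA synthesis genes Gad2 (1.72) and Gad1 (0.87), which medium spiny neurons also express, Dlx5 (1.91), the cholinergic genes Slc5a7 (1.72) and Chat (1.22), and Npy (0.46). Lower were Vip (-3.03), Pvalb (-2.32, 405 ± 35.1 against 70.2 ± 20.5), Cck (-1.92) and Reln (-1.38), while Sst (0.12) did not pass. Of 17 astrocyte markers 4 were lower, led by Gjb6 (-1.12), Gfap (-0.48) and Aldh1l1 (-0.48), and 2 higher. Of 22 microglia markers 4 were lower, such as Lyz2 (-0.99) and Cd74 (-0.70), and 4 higher (2 adjusted over the list alone), such as Ctss (0.44). Camera called none of these lists of interneurons, astrocytes and microglia. Over all probe sets 44.8% passed, so the astrocyte and microglia counts do not set those lists apart.

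Other splits of the same arrays into groups of the same sizes were counted for each comparison. Between the structures, 1 of 100 splits, the real one, gave as many probe sets (8349, highest other 0), and 7 of 100 gave as many as its 14 lists (highest other 16). These splits mix arrays of the structures, so that real differences enter the spread and the lists, and neither count decides. The real counts, taken with the group means, were also set against splits of values without them. There 1 of 100 splits, the real one, gave as many probe sets (highest other 1396), which argues against chance for that count. For the lists called by camera it was 2 of 100, the real one included, a share under 0.05. However, camera called lists in 97 of the other splits, and another split reached the same 14, so single calls by camera stay open. For the 24 lists called by fry it was 1 of 100 (highest other 3), which argues against chance for that count. Fry does not compare a list with other genes, so this does not show that these lists differ more than genes at large. Where the real count is 0 every split gives at least as many, so the splits test nothing for the probe sets of the average (100 of 100, highest other 1), the difference (100 of 100, highest other 1813), the cortex (10 of 10, highest other 3) and the accumbens (10 of 10, highest other 2). The split with 1813 probe sets points to a structure of the arrays beyond the groups. For the lists of the average 17 of 100 splits gave at least the real 9 (highest other 14). For those of the difference 86 of 100 gave at least the real 3 (highest other 16), so chance is not excluded for either. The splits of these comparisons regroup cortex and accumbens arrays independently, so they do not allow for rats shared between the structures. Within a structure 3 arrays against 3 give 10 splits, too few for a share under 0.05: 2 of 10 gave at least 9 lists in the cortex (highest other 11) and 10 of 10 at least 1 list in the accumbens (highest other 12).

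The first pattern weighed is the 4519 probe sets called in the cortex with array weights. With the axis score as a covariate beside the weights 1 call was left (0.0221%), and 3870 of the calls (85.6%) had the sign of the axis found in the accumbens arrays, against 71.4% of all probe sets. Without the heaviest array, cortex vehicle array 3, and with weights estimated anew, 0 calls were left. Of the 10 splits, too few for a share under 0.05, 3 gave as many calls as the real one, and the highest other gave 5386. These values are consistent with calls that come from the shared axis and from the weight of 1 array, and an effect of TsA along the same axis stays open.

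The second pattern is the axis itself. The scores argue against washing together as its whole cause, since 58.5% of the within-group sum of squares of the scores lay between arrays of the same group and wash batch. Cell makeup stays open: among 11 marker lists the largest median change across the axis was -0.312 (microglia), a value that excludes nothing, and genes of red blood cells (Hba-a3 -1.60, Alas2 -1.21, Hbb -1.10, picked after the values were seen) were among the 12 most negative. RNA quality stays open: the score, centred on groups, had r = -0.386 with the GAPDH 3'/5' ratio over 12 arrays (permutation p = 0.4005, rho = -0.434 with permutation p = 0.224, and r = -0.224 without the 2 farthest arrays) and r = 0.475 with that of actin (permutation p = 0.332, rho = 0.308 with permutation p = 0.523, and r = 0.238 without them). With the median signal r was 0.812 (permutation p = 0.00926, adjusted 0.0278 over the 3 relations, and r = 0.697 without the 2 farthest arrays). Here rho was 0.727 (permutation p = 0.0548, adjusted 0.164), and no biological explanation of this relation was tested. The permutations moved the arrays of each group independently, so they do not allow for rats shared between the structures. After quantile normalization the axis held 50.3% of the within-group variance, and its loadings in the 2 structures correlated at 0.708. These values argue against the scaling of the arrays as its whole cause.

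The third pattern is the shift above 0 of cortical glutamatergic markers in the accumbens with TsA (median 0.14, 0 of 30 members past the threshold, adjusted p = 0.837 with an estimated correlation, fry 0.813). Cortical tissue carried along in dissection would raise other genes of the cortex alike. The 35 genes that were at least 4 times higher in the cortex and in no list had a median of 0.0502. Of these genes 22 were above 0, and a bootstrap over the genes gave a 95% interval of -0.0113 to 0.130. That interval includes 0 but leaves out the spread between pools, so it decides nothing. The vehicle pools themselves differed in cortical genes. C1ql3 had signals of 93.5, 30.3 and 202 on accumbens vehicle arrays 1, 2 and 3, and Nptxr 243, 119 and 389. Of the 12 genes named for the largest differences toward the cortex, all but Cyp26b1 and Grp were lowest on array 2 among these. The cause was not tested. Carry-over may contribute and stays open. Within wash batch 3 the list's median was -0.0457, with 1 vehicle array, so wash batch and TsA cannot be told apart here. An effect of TsA stays open as well.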
